A study of Mus musculus with 2 samples.

How the data were processed

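Dimethylation of lysine 4 on histone H3 (H3K4me2) was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in midbrain tissue of mice at postnatal day 0. The data comprise 2 samples of 1 group, which the labels number as biological replicates 1 and 2. Both are pools of male and female tissue, and replicate 1 combined 15 animals. The number of animals in replicate 2 is not given in the sources used here. No control library was analysed here.

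Of the values used, the peak lists were made by the authors on assembly mm10, per the labels. There are 4 lists: one for each replicate, one for the pooled data, and a replicated list. Tested on the files, every peak of the replicated list was a row of the pooled list, and 94.1% of its 34723 peaks overlapped a peak of both replicates by at least 50% of either peak. The other 2040 peaks did not meet that overlap. The deposited signal value of each peak (signal) is the peak's own value from the authors' peak caller, and what it is relative to is not given in the sources used here. The deposited lists also hold the −log10 p and −log10 q of each peak and the position of its summit. The aligner, the peak caller and their versions are not given in the sources used here. The lists hold no read counts, so the depth of each sample is unknown and no interval based on reads is given. The signal was used only to rank or describe peaks within a list. Weak peaks were kept by the authors: q was 0.01 or less for 88.3% of the peaks of replicate 1, 89.6% of replicate 2, 87.7% of the pooled list and 99.6% of the replicated list.

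Peak positions were set against the GRCm38.p6 genome sequence and the GENCODE M21 annotation, both of the assembly that mm10 names. The number of peaks running past a chromosome end was 0. Peaks on the 21 assembled chromosomes were used for gene and feature results. The annotation gave 21853 protein-coding genes with 54361 distinct transcription start sites (TSSs) of protein-coding transcripts. Coordinates are given from 1. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.

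Replicates were compared by the percent of peaks overlapping the other replicate by at least 1 bp, with 95% Wilson intervals over peaks, and by shared base pairs. The intervals treat peaks as independent, although a site can be split into several peaks. They do not describe the spread between animals. Chance was estimated from 100 random placements of the peaks within chromosomes, outside assembly gaps. Each peak was assigned by its midpoint to a promoter (within 1 kb of a TSS), an exon, an intron or intergenic sequence. A gene was called marked where a replicated peak lay within 1 kb of any of its TSSs. Replicated peaks 1 kb or less apart were joined into domains, and a marked gene took the width of its widest domain at a TSS. Neighbouring genes can share a domain. Replicated peaks more than 1 kb from every TSS were called distal. They were assigned to the gene with the nearest TSS within 100 kb, which is an assignment by distance only. Distal peaks were not joined, so they could lie within the TSS domain of their gene. A TSS was called CpG-rich where the 500 bp on each side had an observed over expected CpG ratio of at least 0.6 and a GC fraction of at least 0.5, taking for each gene the TSS with the highest ratio.

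A set of 31 gene lists was fixed before the data were examined, along with the tests and the alternatives. It held 29 lists of named genes for neuron classes, glia, vessels, blood, brain regions, Hox genes, tissues outside the brain and gene classes, plus the olfactory receptors and families of developmental transcription factors chosen by symbol. Of the 12 erythroid genes, 1 (Ahsp) was not found in the annotation. Lists overlap: 117 of the 299 developmental transcription factors are in another list. Marking of each list was compared with all other protein-coding genes by a two-sided Fisher exact test. Median domain widths were compared with 100000 random draws of as many marked genes, in lists with at least 5 marked members, and mean distal peak numbers with 100000 draws matched on the span between neighbouring TSSs (in 10 classes) (10000 draws for the olfactory receptors), by two-sided permutation tests. All p-values were adjusted by the Benjamini-Hochberg method over the lists. These tests are across genes, which are not independent replicates, so their p-values describe the lists in these data and not the spread between animals. With 2 replicates no test of a difference between samples could be made, and the spread between replicate lists is given as mean ± SD (n = 2).

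The share of distal peaks with a match to each of 10 sequence motifs was taken in the 400 bp around the summit. It was compared with windows 3 kb to each side that overlapped no replicated peak. The ratio used both flanks. The exact McNemar test paired each peak with 1 flank, picked at random where both were usable. Peaks are not independent replicates, so its p-values describe these peaks and not the spread between animals. Up to 20 reorderings of each motif without a CpG gave a range of ratios for sequences of the same base composition. Only the motif and its reverse complement were left out, so a reordering may itself be another motif or a shifted copy. A ratio within that range therefore does not show that composition explains it. A motif was called where the adjusted p was under 0.05 and the ratio lay beyond every reordering on its own side of 1. The requirement on the side of 1 was added after the first values were seen. Without it the homeodomain motif would also have been called.

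The genes named in the text were chosen by a rule fixed before the data were examined: 20 genes of the midbrain and of contrasting regions or lineages; the 10 widest TSS domains; for each list past a threshold, its 3 widest members and up to 2 members without a TSS peak; the 5 genes with the most distal peaks; and the 5 replicated peaks with the highest signal. Other names are given with a statement that they were chosen after their values were seen. Near-identical gene copies can share reads, so the percent of 31-mers found once in the genome was computed for the TSS windows of several gene sets.

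The scripts were tested on simulated data with known answers. In a copy of the replicate 1 list of 50497 peaks, all kept peaks (100%) were found again and 1.85% of the moved peaks overlapped by chance. Over 21853 genes, 18 of 20 lists with changed marking were called and 1 of 20 unchanged lists. For domain width 12 of 15 changed and 0 of 20 unchanged lists were called, and for distal peaks 20 of 20 and 0 of 20. Of 300 planted CTCF matches in 2000 windows, 300 were found.

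The alternatives were each replicate list alone, a q of 0.01 or less, the pooled list, other overlap rules, windows of 500 bp and 2.5 kb, joining distances of 0 and 3 kb, assignment within 50 or 500 kb, comparison within CpG classes, a stricter CpG class and other motif windows. Peaks on contigs outside the assembled chromosomes were left out of gene-level results.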

Results

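H3K4me2, a histone mark found at promoters and enhancers, was mapped in the midbrain of newborn mice in 2 biological replicates of 1 group. The design holds no contrast between conditions. It addresses where the mark lay in this tissue, at which genes, and how far both replicates gave the same sites. Replicate 1 had 50514 peaks covering 46.8 Mb and replicate 2 had 48101 peaks covering 47.8 Mb. The replicated list, used for the values below unless stated, had 34723 peaks covering 49.6 Mb, with a median width of 1007 bp. Read depth is unknown from these files.

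Strong H3K4me2 sites were shared between the replicates. Of the peaks of replicate 1, 39085 (77.4%, 95% Wilson interval 77.0 to 77.7) overlapped a peak of replicate 2. Of the peaks of replicate 2, 37139 (77.2%, interval 76.8 to 77.6) overlapped a peak of replicate 1. With shuffled positions these shares were 3.74% and 3.91%. The shared bases were 76.5% of all bases covered in either list, against 0.99% after shuffling. Each list was split by signal into 10 groups of equal size. In the 3 highest groups 100% of the peaks of each replicate had a partner, and in the lowest group 36% and 36.6% had one. Peaks without a partner were narrow, with a median of 195 bp in replicate 1 and 214 bp in replicate 2, against 759 and 831 bp for shared peaks. When an overlap of 50% of both peaks was required, the lowest group had 13.6% in place of 36.3% on average.

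**Figure D1:**
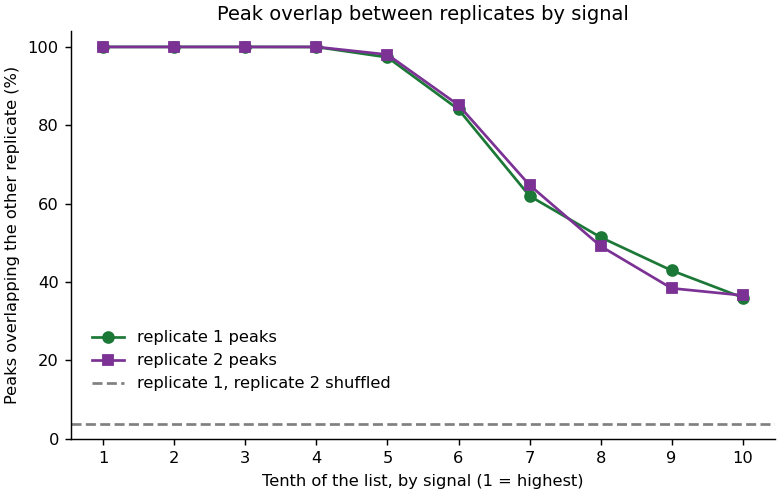
Percent of the peaks of each replicate that overlap a peak of the other by at least 1 bp (y axis), by signal group (x axis; 10 groups of equal size ranked by the authors' signal value, 1 is the highest). Overlap is 100% in the first 3 groups and falls to 36% and 36.6% in the lowest, above the 3.74% found with shuffled positions (dashed line).

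The 5 replicated peaks with the highest signal each covered the TSS of a gene. They lay at Rreb1, a zinc finger transcription factor gene (chromosome 13, 37777781 to 37779703, mm10; signal 75.8), at the collagen gene Col27a1 (chromosome 4, 63213789 to 63217151; signal 70.1), at E2f2, a cell cycle transcription factor gene (chromosome 4, 136171548 to 136173477; signal 67), at the immediate early gene Egr1 (chromosome 18, 34858954 to 34863677; signal 66.8) and at Oxr1, a gene of oxidation resistance (chromosome 15, 41788103 to 41790055; signal 66.5). The Rreb1 peak ranked 2 in replicate 1 and 1 in replicate 2. The Egr1 peak ranked 18 and 5.

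H3K4me2 peaks were concentrated at promoters. By midpoint, 15043 of 34708 replicated peaks (43.3%) lay within 1 kb of a protein-coding TSS, which was 16.4-fold above the shuffled mean of 2.65% (range 2.44 to 2.84%). Exons held 4.06% of the peaks, 1.60-fold above the shuffled mean. Introns held 26.8% and intergenic sequence 25.8%, which were 0.724-fold and 0.446-fold of the shuffled means. The promoter share was 35.7% ± 0.232 (SD, n = 2) in the separate replicate lists, which hold more weak peaks, and 31.5% in the pooled list. The 17839 distal peaks had a median width of 597 bp and a median signal of 5.65, against 1877 bp and 25.5 for the other peaks.

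**Figure D2:**
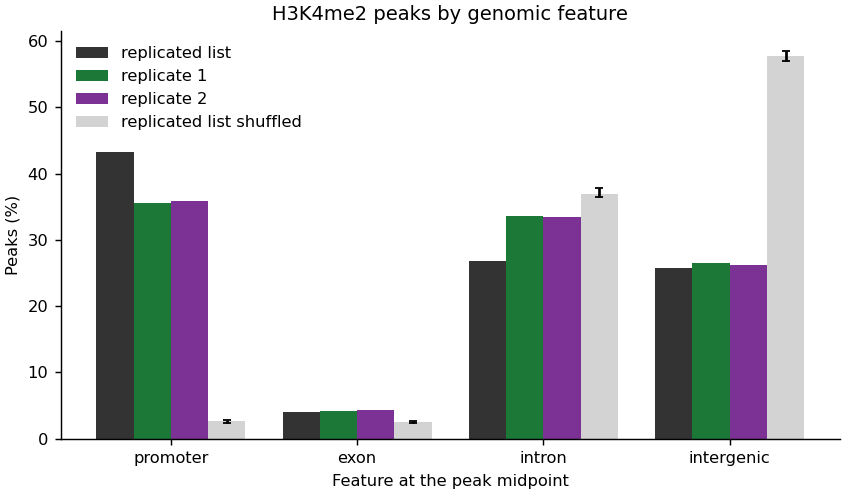
Percent of peaks (y axis) whose midpoint lies in a promoter, exon, intron or intergenic sequence (x axis), for the replicated list, each replicate list and the replicated list at shuffled positions (mean of 100 shuffles, with bars from the lowest to the highest). Promoters hold 43.3% of replicated peaks against 2.65% after shuffling.

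A TSS peak was present at 14445 of 21853 protein-coding genes (66.1%). Each replicate list alone gave 66.7% ± 0.107 (SD, n = 2), and 14406 genes were marked in both lists against 329 in only 1 of them. Sequence context separated marked from unmarked genes: 10739 of 10889 genes with a CpG-rich TSS (98.6%) were marked, against 3706 of 10964 others (33.8%; odds ratio 140, Fisher exact test). Marked genes had a median domain of 2494 bp (middle range 1826 to 3494 bp). The SD between replicates of a gene's domain width had a median of 125 bp, over the 14406 genes marked in both.

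Pan-neuronal, GABAergic, glutamatergic and neural progenitor genes carried TSS peaks more often than other genes. All 20 pan-neuronal genes were marked (adjusted p = 0.002, Fisher exact test), as were all 18 neural progenitor genes (adjusted Fisher p = 0.0025) and all 16 genes of GABAergic neurons (adjusted Fisher p = 0.0054). These 3 lists also differed from genes of the same CpG class (adjusted Fisher p = 0.0013, 0.0248 and 0.0416). With only the 5'-most TSS of each gene the GABAergic call was lost (87.5%), as were the forebrain and imprinted calls given below (75% each). The glutamatergic list had 15 of 16 genes marked (adjusted Fisher p = 0.0249; 0.0838 within CpG class), all but Neurod6, a transcription factor of forebrain excitatory neurons, which had a TSS peak of 204 bp ± 31.1 (SD, n = 2) in the replicate lists. Of the midbrain patterning genes 17 of 18 were marked (adjusted Fisher p = 0.0181; 0.384 within CpG class). The exception was the signalling gene Wnt1 (chromosome 15, 98789857 to 98793837), which had a TSS peak in only 1 replicate list. Lists of general function were marked throughout: 14 of 14 cell cycle genes, 14 of 14 immediate early genes, 16 of 16 housekeeping genes and 12 of 12 Parkinson disease genes, with 15 of 16 imprinted genes, where Ndn was the exception (adjusted Fisher p = 0.0079, 0.0079, 0.0054, 0.0185 and 0.0249). None of these 5 differed from genes of the same CpG class (adjusted Fisher p from 0.094 to 0.512). This comparison had little room to show more marking, since 98.6% of CpG-rich genes were marked. In the order above, 12 of 14, 13 of 14, 13 of 16, 10 of 12 and 12 of 16 genes were CpG-rich. So were 15 of 18 midbrain patterning genes. The comparison therefore does not set these lists apart from the neuronal ones.

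The genes of dopaminergic neurons, a small midbrain population, did not differ from other genes. Of their 20 genes 17 were marked (85.0%; adjusted Fisher p = 0.12). The transporter gene Slc6a3 (ENSMUSG00000021609) had a domain of 1166 bp, and the transcription factor genes Pitx3, Nr4a2, Foxa2 and Lmx1b had domains of 1906, 3976, 3209 and 3654 bp. Th, which encodes the rate-limiting enzyme of dopamine synthesis (chromosome 7, 142892752 to 142931128), had no peak within 1 kb of a TSS in either replicate, and the nearest replicated peak lay 36086 bp from the gene, at Ascl2. Ddc and Aldh1a1, named after their values were seen, had no replicated TSS peak. With the pooled list this list passed the threshold (90%). Serotonergic genes (10 of 12; adjusted Fisher p = 0.413) and cholinergic and motor neuron genes (11 of 12; adjusted Fisher p = 0.0912) did not differ from other genes, though with the pooled list all 12 serotonergic genes were marked and the list passed.

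Lists of microglia, blood cells, germ cells and cells outside the brain were marked less often. Of 16 microglia genes 1 was marked (adjusted Fisher p = 1e-05; 0.0221 within CpG class): Hexb, which encodes a lysosomal enzyme made in many cells. Replicate 1 alone marked 3 of the 16. Cx3cr1, Aif1 and C1qa had no TSS peak in either replicate. The erythroid list had 3 of 11 genes marked, the skeletal muscle list 4 of 15, the epidermis list 2 of 12, the hepatocyte list 2 of 17, the lymphocyte list 2 of 14 and the photoreceptor list 0 of 12 (adjusted Fisher p = 0.018, 0.0054, 0.0024, 3.5e-05, 5.09e-04 and 1.77e-05). The unmarked erythroid genes include the globin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt, named after their values were seen. They are near-identical copies whose share of unique 31-mers was not computed, so their lack of a peak is uncertain. Alb, the serum albumin gene, and Crx, a photoreceptor transcription factor gene, were unmarked, while the muscle regulator Myod1 had a domain of 1723 bp. The lymphocyte exceptions were Foxp3 and Pax5, and Pax5 is also a midbrain patterning gene (6421 bp). Within CpG classes the erythroid, skeletal muscle, epidermis and hepatocyte lists no longer differed (adjusted Fisher p from 0.168 to 0.812), and the skeletal muscle call was also lost with a 2.5 kb window. Of 14 germ cell genes 3 were marked (adjusted Fisher p = 0.0025; 1.97e-05 within CpG class), and Ddx4 and Mael were not. Of 1134 olfactory receptor genes 4 (0.353%) were marked, Olfr94 with 1618 bp being the widest. In the TSS windows of 100 random olfactory receptors a median of 91.0% of 31-mers were unique, and 1 of the 100 had under 50%.

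Glial and vascular lists did not differ from other genes in the replicated list. Marked were 13 of 15 astrocyte genes, 10 of 15 oligodendrocyte lineage genes, 9 of 14 endothelial genes, 11 of 12 mural cell genes and 10 of 14 genes of meninges and fibroblasts (adjusted Fisher p = 0.128, 1, 1, 0.0912 and 0.838). Gfap and S100b, of astrocytes, and Gpr17 and Mag, of the oligodendrocyte lineage, had no replicated TSS peak. In replicate 2 alone, S100b and Gpr17 had one. With replicate 2 alone and with the pooled list, the astrocyte and mural cell lists passed as marked more often (93.3% and 100%). Mural cell genes, of which 2 were CpG-rich, were marked more often than genes of the same CpG class (adjusted Fisher p = 0.0024).

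Transcription factors of brain regions were mostly marked. The developmental families had 248 of 299 genes marked (82.9%; adjusted Fisher p = 1.45e-09; 0.848 within CpG class), the forebrain list 18 of 20 (adjusted Fisher p = 0.0429; 1 within CpG class) and the hindbrain list 13 of 17 (adjusted Fisher p = 0.498). Tbr1 and Fezf2, of the cortex, had no replicated TSS peak. Fezf2 had a TSS peak in both replicate lists (296 bp ± 13.4, SD, n = 2). Tbr1 had a TSS peak in replicate 2 alone (232 bp), where all 20 forebrain genes were marked. Hoxb1, of the hindbrain, was unmarked in the replicated list and in both replicate lists. The Hox genes, which pattern the hindbrain and trunk, went the other way: 17 of 39 were marked (43.6%; adjusted Fisher p = 0.0114; 7.53e-15 within CpG class), although 28 of them had a CpG-rich TSS. Hoxa9, Hoxa10 and Hoxa11 were without a TSS peak in either replicate. The Hox call was lost with replicate 2 alone, the pooled list or a 2.5 kb window, and 48.7% ± 7.25 (SD, n = 2) of Hox genes were marked in the replicate lists.

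**Figure D3:**
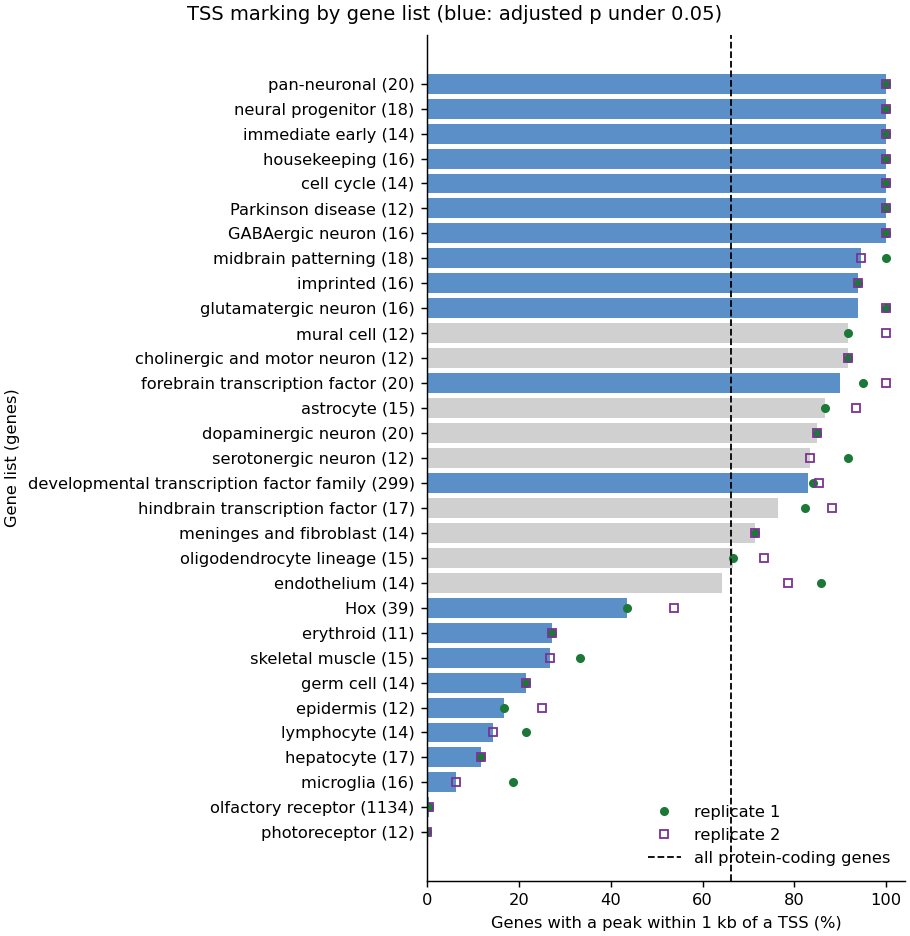
Percent of the genes of each of 31 lists with a peak within 1 kb of a TSS (x axis; y axis: list, with its number of genes). Bars show the replicated list, blue where the adjusted p of the Fisher exact test is under 0.05, symbols show each replicate list and the dashed line marks 66.1%. All pan-neuronal genes are marked, against 1 of 16 microglia genes.

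GABAergic, glutamatergic and pan-neuronal genes lay in wide H3K4me2 domains. Of 22 lists tested 8 had wider and 4 narrower domains than random marked genes (permutation test). The median was 9018 bp for GABAergic, 7264 bp for glutamatergic and 5812 bp for pan-neuronal genes, against about 2530 bp in random lists (adjusted permutation p = 1.1e-04 each, from the smallest p the draws can give, 2e-05). Midbrain patterning genes had 4925 bp and neural progenitor genes 4654 bp (adjusted permutation p = 2.2e-04 each), astrocyte genes 5041 bp (adjusted permutation p = 5.66e-04), immediate early genes 4542 bp (adjusted permutation p = 7.15e-04) and imprinted genes 3589 bp (adjusted permutation p = 0.0474; 0.0595 matched on CpG content and 0.108 with single peaks). The order of the lists depended on how peaks were joined: with single peaks the pan-neuronal (4918 bp) and immediate early lists (4165 bp) had the highest medians, and with joining within 3 kb the glutamatergic (12101 bp) and GABAergic lists (11907 bp). Separate replicates gave 8900 bp ± 198 for GABAergic genes and 8569 bp ± 2222 for glutamatergic genes (SD, n = 2).

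Otx2, a determinant of fore- and midbrain (chromosome 14, 48657677 to 48673819), lay in a domain of 20175 bp (20197 ± 29.7, SD, n = 2). En1, required for the mid- and hindbrain (chromosome 1, 120602418 to 120607992), had 14939 bp (15046 ± 821), En2 7948 bp and Pax7, of the dorsal midbrain, 13841 bp (12382 ± 1795). The GABAergic selector Gata3 (chromosome 2, 9857078 to 9890034) had 22947 bp (23769 ± 1442), a domain shared with the predicted genes 4930412O13Rik and 9230102O04Rik. Gad1, which makes GABA, had 13118 bp and Slc17a6, a vesicular glutamate transporter gene, 13865 bp. Other GABAergic and glutamatergic regulators with wide domains were Lhx1 (20491 bp), Lhx5 (17153 bp), Lhx9 (21641 bp) and Tcf7l2 (17252 bp). Among pan-neuronal genes Celf4 had 13162 bp, Elavl4 9798 bp and Tubb3 8230 bp. The astrocyte list was led by Nfib (21631 bp) and Nfia (11427 bp), and the immediate early list by Jund (6753 bp) and Egr3 (6671 bp). The progenitor gene Sox2 had 18254 bp in the replicated list but 19824 bp in replicate 1 and 3395 bp in replicate 2.

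The widest domain of all lay at Zfhx3, a homeodomain transcription factor gene (28052 bp; 32152 ± 654, SD, n = 2), followed by Nr2f2 (25660 bp; 22140 ± 5427), Meis2 (24449 bp), Ebf3 (23269 bp) and Pou3f3 (23008 bp). Lhx2 (21808 bp; 16214 ± 8878) and Zic1 (21681 bp, shared with Zic4; 16957 ± 6421) completed the 10 widest with Gata3 and its 2 neighbours. Each depended on the replicate: Lhx2 had 22491 bp in replicate 1 and 9936 bp in replicate 2, and Zic1 12417 and 21497 bp.

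Narrower domains than in random lists were found at Hox genes (866 bp; adjusted permutation p = 1.1e-04), cholinergic and motor neuron genes (1364 bp; adjusted permutation p = 0.0036), mural cell genes (1654 bp; adjusted permutation p = 0.0455) and forebrain transcription factors (1864 bp; adjusted permutation p = 0.0474). Hoxa1 had 1766 bp. Among cholinergic and motor neuron genes Ache had 5403 bp (5114 ± 177, SD, n = 2) and Chat and Slc18a3 shared 2424 bp. The telencephalic gene Foxg1 had 1012 bp (870 ± 161, SD, n = 2). Forebrain members differed among themselves, since Bcl11b (17040 bp; 16992 ± 48.8) and Emx2 (8639 bp; 9462 ± 1965) had wide domains. Six3 had 10603 bp, with 12461 bp in replicate 1 and 4722 bp in replicate 2. The forebrain call was lost when peaks were joined within 3 kb or when means of log2 widths were compared, the cholinergic call with replicate 1 alone, with the pooled list and with 3 kb joining, and the mural cell call with replicate 1 alone, single peaks or CpG matching. Dopaminergic (1911 bp), serotonergic (2871 bp), cell cycle (1900 bp), oligodendrocyte lineage (2998 bp), endothelial (2172 bp), meningeal and fibroblast (2082 bp), hindbrain (2889 bp), housekeeping (3122 bp), Parkinson disease (3156 bp) and developmental transcription factor genes (2380 bp) did not differ from random lists (adjusted permutation p from 0.0887 to 0.469). Several of these depended on the processing. Developmental transcription factors passed as wider when peaks were joined within 3 kb (3473 bp) or by mean log2 width, and as narrower when peaks were not joined (1805 bp). Matched on CpG content, dopaminergic and cell cycle genes passed as narrower (adjusted permutation p = 0.0442 and 0.0119). Oligodendrocyte lineage genes passed as wider with replicate 2 alone and with the pooled list, hindbrain genes when joined within 3 kb or by mean log2 width, and serotonergic genes when joined within 3 kb. Endothelial genes passed as narrower with replicate 1 alone.

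**Figure D4:**
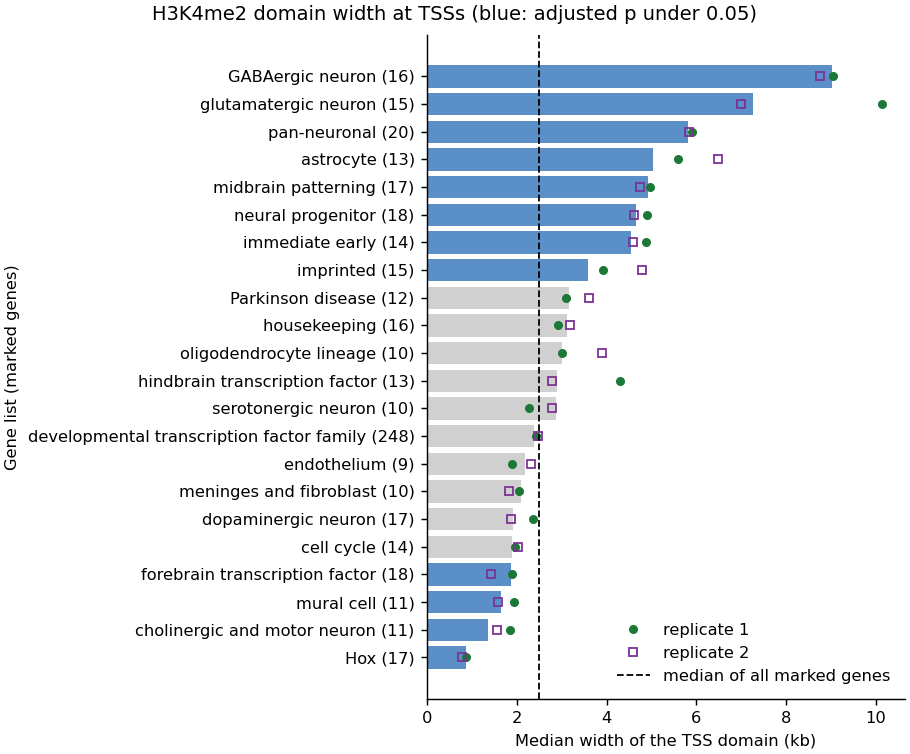
Median width in kb of the H3K4me2 domain at the TSSs of the marked genes of each list (x axis; y axis: list, with its number of marked genes). Bars show the replicated list, blue where the adjusted p of the permutation test is under 0.05, symbols show each replicate list and the dashed line marks the median of all marked genes, 2494 bp. In the replicated list GABAergic genes have a median of 9018 bp and Hox genes of 866 bp.

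**Figure D5:**
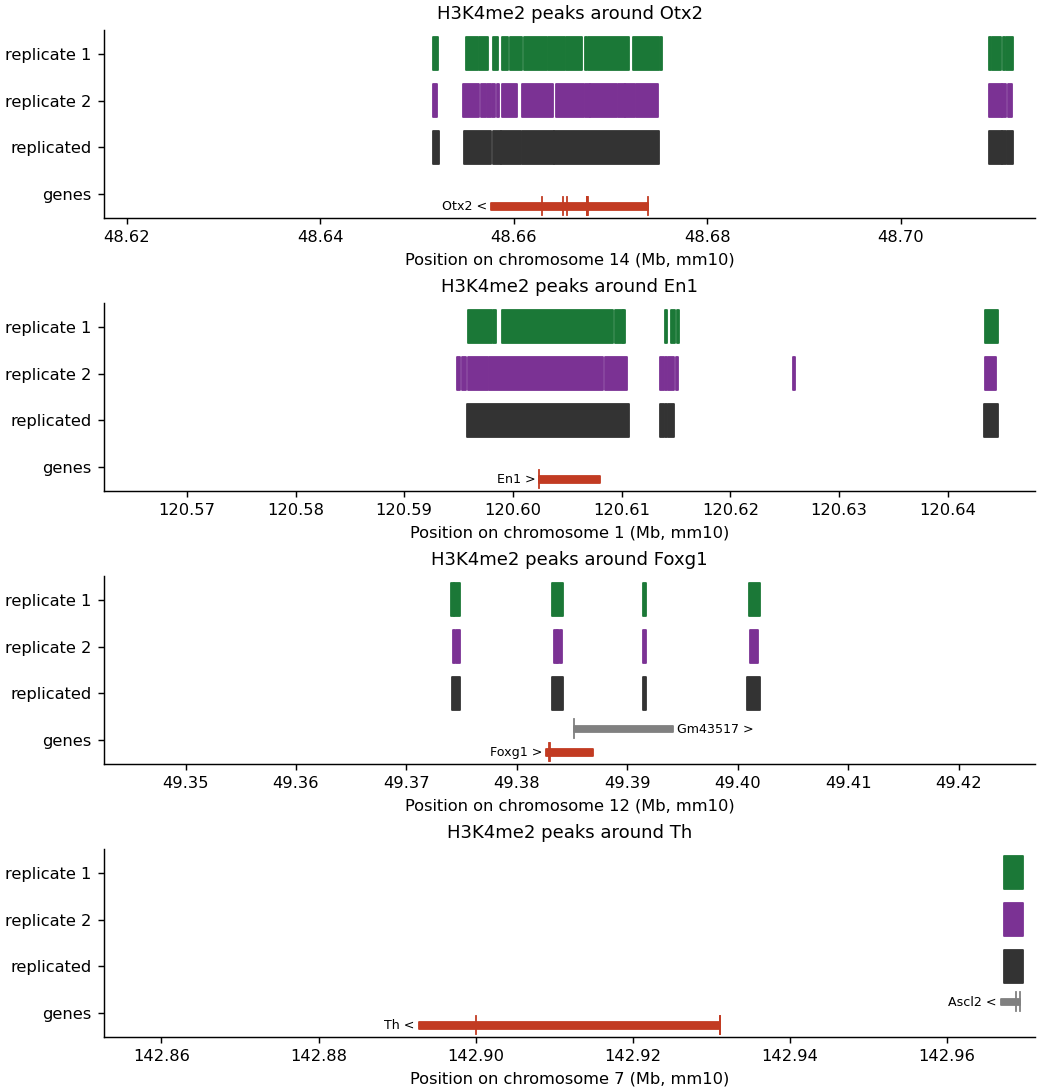
Peaks of each replicate and of the replicated list around Otx2, En1, Foxg1 and Th, with 40 kb on each side of the gene (x axis: position in Mb, mm10). Gene bodies are bars, with the named gene in red, vertical ticks at TSSs and an arrowhead for the strand. Otx2 and En1 lie under domains of 20175 and 14939 bp, Foxg1 has a peak domain of 1012 bp, and Th has no peak within 5 kb in any list. The 1 peak of each list in the Th panel lies at Ascl2.

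Distal peaks per gene were most numerous in the midbrain patterning, glutamatergic and neural progenitor lists. Of 17839 distal peaks 14598 (81.8%) were assigned to a gene, a mean of 0.668 per gene. In 12 of 31 lists the mean exceeded that of random lists of matched span, and in 1 it was lower (permutation test). Midbrain patterning genes had 6.06 distal peaks per gene against 1.24 in random lists, glutamatergic genes 5.81 against 1.24, neural progenitor genes 4.94 against 0.977 and developmental transcription factors 2.75 against 0.93 (adjusted permutation p = 1.55e-04 each). The forebrain list had 3.85, the GABAergic 3.38, the astrocyte 3.27, the hindbrain 3.24, the pan-neuronal 3.20, the immediate early 2.64 and the oligodendrocyte lineage list 2.47 (adjusted permutation p from 8.27e-04 to 0.003). Housekeeping genes had 1.12 (adjusted permutation p = 0.0384), a call lost in 4 of the 8 alternatives. Olfactory receptors had 0.0273 against 0.294 (adjusted permutation p = 8.86e-04). The replicate lists gave higher numbers and another order. Means (SD, n = 2) were 9.69 ± 1.24 for glutamatergic, 8.75 ± 0.196 for midbrain patterning and 7.39 ± 0.55 for neural progenitor genes. They were 6.37 ± 0.141 for astrocyte and 6.33 ± 0.743 for pan-neuronal genes. The replicate lists count weaker peaks, but they also split some sites into more peaks. Around Otx2 both had 17 peaks, over 20435 and 20708 bp, against 9 over 22810 bp in the replicated list. Around En1 they had 9 and 11 against 5, around Foxg1 5 and 7 against 4, and around Th each list had 1. Distal numbers therefore depend on how a site is split, and the share due to weaker peaks was not computed.

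Around single genes, En2 had 9 distal peaks, Otx2 8, Lmx1b 7, Pax7 6 and Slc17a6 6. Olig2, the oligodendrocyte lineage regulator, had 8 and Emx2 had 10. The most were assigned to Zfhx3 and Gse1 (22 each), the axon guidance ligand gene Efna5 (21), Zic4 (20) and the adhesion receptor gene Adgrl2 (18). In the replicate lists these numbers were higher, at 39 ± 4.24 for Zfhx3 and 43 ± 12.7 for Gse1 (SD, n = 2). Th, Slc6a3, Pitx3, Hoxa9, Cx3cr1 and Alb had 0. Some distal peaks were parts of the gene's own TSS domain. At Otx2 these included the replicated peaks from 48654807 to 48657636 and from 48657836 to 48658643. Distal numbers and domain widths are therefore not separate measures.

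The remaining 18 lists did not pass the test. Dopaminergic genes had 1.95 distal peaks per gene against 1.19 (adjusted permutation p = 0.199), imprinted genes 2.25 against 1.02 (adjusted permutation p = 0.0521), endothelial genes 1.93 and serotonergic genes 1.75. Meningeal and fibroblast genes had 1.36, skeletal muscle 0.933, mural cell 0.917, lymphocyte 0.857, cholinergic and motor neuron 0.833, microglia 0.688 and Parkinson disease genes 0.667. Cell cycle, photoreceptor and epidermis genes had 0.5 each, erythroid 0.364, Hox 0.359, hepatocyte 0.235 and germ cell genes 0.0714. Imprinted genes passed as higher in 5 of the 8 alternatives, and germ cell genes as lower in 4 of 8. Without matching on span, dopaminergic and endothelial genes passed as higher.

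Among 10 motifs, matches to that of CTCF, an insulator and loop anchor protein, were the most enriched in distal peaks. A match lay within 400 bp around the summit in 2.01% of 17437 peaks and in 0.255% of flanking windows (ratio 7.89; adjusted p = 1.56e-65, exact McNemar test; highest of 20 reorderings 3.05). In the central 200 bp, however, the ratio was 0.778 (adjusted exact p = 0.678; at most 5.84e-56 in the other alternatives). The NFI palindrome was enriched 4.97-fold (highest reordering 2.64) but was rare, in 0.0803% of peaks and 0.0161% of flanking windows. In the pairs tested, 14 peaks and 3 flanks held the only match (adjusted exact p = 0.0159). The call was lost without replicate 2, with 200 bp windows and beyond 5 kb from a TSS. The E-box CAGCTG (ratio 1.58), RFX (1.36) and OCT (1.27) motifs had p-values under 0.05 and ratios within the range of their reorderings (highest 1.72, 1.47 and 1.29). With either replicate list alone or flanks at 10 kb, OCT exceeded its reorderings. The homeodomain core TAATTA was less frequent in peaks than in flanks (ratio 0.909) and lay above all 13 of its reorderings (highest 0.824). Its adjusted p was 0.0019 (exact McNemar test), and only the later requirement on the side of 1 kept it from being called. SOX, bZIP, GATA and E-box CAGATG motifs had ratios of 0.910, 0.826, 0.787 and 0.963, all within the range of their reorderings. Peaks were richer in GC than flanks (51.1% against 44.8%).

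Peak density differed between chromosomes. The autosomes had 10.2 (chromosome 14) to 21.4 (chromosome 11) replicated peaks per Mb, with a median of 14.2. The X chromosome had 5.93 per Mb, 0.417 of the autosome median. The replicate lists gave a ratio of 0.392 ± 0.0085 (SD, n = 2). The Y chromosome held 7 replicated peaks. With the pooled list the X ratio was 0.355.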

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

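The test of pooled peaks at Hox genes was chosen only after the result was seen; the other tests in this part were chosen before. In data outside the main measurement, 15 replicated peaks lay on contigs outside the assembled chromosomes, above the 3 that a count of 0 allows. Of these, 7 lay on a contig assigned to the X chromosome without a position. The contigs are part of the assembly, so some peaks are to be expected there, and no expected number was computed. Replicate 1 had 17 and replicate 2 had 18. No test was made of what they mark. The design gives 1 group, so no biological explanation was tested here for Th, for the Hox genes only their paralogue groups were compared (under the other observations), and for the X chromosome only its number of copies was examined.

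Of 39 Hox genes 22 lacked a replicated TSS peak. Sequence on which reads cannot be placed is argued against, since the TSS windows of these 22 genes had a median of 99.9% unique 31-mers. Pooled peaks left out of the replicated list were not the whole cause. Of the 22 genes, 22.7% (5) had a pooled peak at a TSS, and 16 had no peak in either replicate. A state of these promoters in the midbrain stays open and was not tested.

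Th had no TSS peak in any of the 4 lists. Its TSS windows had 97.7% unique 31-mers, which argues against unplaceable sequence, and 0 of the 4 lists had a peak within 5 kb of the gene, which argues against a marked site away from the annotated TSSs. The share of dopaminergic cells was not measured. The dopaminergic genes Slc6a3 and Pitx3 had TSS peaks in both replicates (signal 38.0 and 53.4 in the replicated list). Of the 20 genes of the list 17 were marked, and 14 were CpG-rich. Which cells these peaks came from is unknown, so they do not decide whether a small share could matter. Neither Th (CpG ratio 0.266) nor Slc6a3 (0.552) nor Pitx3 (0.559) had a CpG-rich TSS. Of genes without one, 33.8% were marked. Ddc and Aldh1a1 had no replicated TSS peak. With the pooled list every gene of the serotonergic list, which holds Ddc, was marked, so Ddc differed from Th there. Why Th lacked a TSS peak stays open.

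The X chromosome had 0.417 of the peak density of the autosome median. Fewer copies of X in pools that include males could lower its signal, and the median signal at CpG-rich TSSs on X was 56.0% of that on autosomes (16.7 against 29.8; 57.4% and 56.3% in the replicates). This goes with that explanation but does not decide it. The ratio of males to females and what the signal is relative to are not given, so the value that copy number alone would give is unknown. Other causes of a lower signal on X were not examined. Gene content stays open too, since 27.4% of X genes had a CpG-rich TSS against 51.3% of autosomal genes. Within each class the marked shares were close. They were 96.5% on X against 98.7% for CpG-rich genes, and 34.0% against 34.4% for the others.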

How the results depend on the processing

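All alternatives were planned. No paired analysis was possible because there is 1 group. For the results that answer the design's questions, 36 of 61 values under the alternatives kept within the spread between replicates or within 1.5 times the count, and 25 did not. For peak overlap that spread was only the SD of the 2 directions of 1 comparison (0.116 over all peaks). Small shifts in overlap were therefore counted among the values that did not keep. The cause was not tested unless stated.

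Mean overlap of the replicates was 77.3%. It was 59.3% with a reciprocal 50% overlap and 75.6% with 25% of the shorter peak, both stricter rules by construction. It was 80.2% at a q of 0.01 or less, 80.3% with peaks joined within 1 kb and 77.0% on autosomes. The lowest of 10 signal groups had 36.3%, against 34.5% when ranked by −log10 p and 13.6% with reciprocal overlap.

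The promoter share of 43.3% was 35.5 to 35.9% without one replicate, 31.5% in the pooled list, 29.9% and 53.2% with windows of 500 bp and 2.5 kb, and 50.6% by base pairs. Genes marked, 66.1%, were 66.6 to 66.8% without one replicate, 67.4% in the pooled list, 65.5% and 67.2% with the 500 bp and 2.5 kb windows and 63.5% with only the 5'-most TSS. The X ratio of 0.417 was 0.386 to 0.398 without one replicate and 0.355 in the pooled list.

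Of 22 lists that differed in marking, 9 did so within the same CpG class, where 10 lists passed. Numbers of lists stayed within 1.5 times in all other alternatives for marking, width and distal peaks. Of 2 motifs called, 0 were called in the 200 bp window and 1 beyond 5 kb from a TSS.

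Of 732 values for single lists and motifs, 662 kept their direction and side of the threshold, 35 lost the threshold, 30 gained it and 5 reversed. Reversed were forebrain transcription factor marking, which was 90% and lower than in genes of the same CpG class, and width when joined within 3 kb (2927 bp), neither past the threshold. Developmental transcription factors became wider, and past the threshold, when peaks were joined within 3 kb (3473 bp) and by mean log2 width (11.40), and narrower past it when peaks were not joined (1805 bp). The CTCF ratio was 0.778 in the 200 bp window, not past the threshold. Read depth is unknown, so what it limits could not be given.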

Other observations

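The tests of CTCF positions, the widest domains, unmarked CpG-rich genes and Hox paralogue groups were chosen only after the results were seen, and the test of lncRNA TSSs before. The 100 widest TSS domains, of at least 11164 bp, belonged to 26 genes of the developmental transcription factor list and 74 other genes. That list was chosen by symbol, so the 74 include further transcription factor genes, such as Zfhx3. Among the 14345 other marked genes 222 (1.55%) were in the list (odds ratio 22.4, p = 7.71e-24, Fisher exact test). Neighbouring genes that share a domain were counted separately. Members of this list spread both ways: 10% had domains under 767 bp and 10% over 11682 bp, against 1258 and 4901 bp for all marked genes, with peaks joined within 1 kb.

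Of 8960 intergenic replicated peaks 870 (9.71%) lay within 1 kb of the TSS of an annotated long noncoding RNA, against 0.897% after shuffling (range 0.749 to 1.06%). The replicate lists gave 8.46% and 9.0%. Such promoters may account for a small part of the peaks away from protein-coding genes.

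CTCF matches were scarce at the summits of distal peaks and frequent beside them. There were 7.29 per Mb within 100 bp of the summit, 98.7 at 100 to 200 bp, 58.9 at 200 to 300 bp and 6.96 at 750 to 1000 bp. The ratio of the second to the first was 13.5, and both replicate lists showed the same order (61.6 against 11 and 74.8 against 10.5 per Mb). This restates in finer steps the difference between the 400 bp and 200 bp windows and does not explain it.

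Of 150 CpG-rich genes without a replicated TSS peak, 18 were Hox or germ cell genes, out of 34 such CpG-rich genes (odds ratio 91.4). The 2 lists were picked because their marking within the CpG class was already low, so this describes the 150 genes and is no further evidence. No peak in either replicate was found at 125 of the 150. Under 50% unique 31-mers around the TSSs were found at 67 of the 150, against 2 of 300 random marked genes. In the lists, 123 of the 150 had no place.

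Lower-numbered Hox paralogues, which act further forward in the body, could have been marked more often, but the test did not separate them. In groups 1 to 5, 7 of 15 genes were marked, and in groups 6 to 13, 10 of 24 (odds ratio 1.23, one-sided p = 0.509, Fisher exact test). By cluster, 5 of 11 genes were marked in Hoxa, 3 of 10 in Hoxb, 3 of 9 in Hoxc and 6 of 9 in Hoxd.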
